A study of Bos taurus with 60 samples.

How the data were processed

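The series holds 60 small RNA libraries of bovine intestinal tissue, 1 per animal and region, made per the labels from snap-frozen biopsies with the mirVana total RNA kit and the TruSeq small RNA kit. The protocol text names rectal tissue for every library, while the tissue labels name 6 regions, and the tissue labels were used. The deposited table holds raw read counts per mature miRNA, which was tested on its values: they are whole numbers, and the column sums differ between libraries. Bowtie and edgeR are named in the processing notes of the authors. Their versions and roles, the genome build, the miRNA annotation and the treatment of reads that match several miRNAs are not given in the sources used here. How counts were divided among near-identical miRNAs, such as the miR-2284/miR-2285, miR-378 and miR-17/106/20 families, is therefore uncertain. No genome coordinates are printed, since the build behind the counts is not named, and the reference gene table (assembly ARS-UCD2.0) served only for names and for which genes neighbour each other. Of 608 miRNA names, 602 were matched to the reference and 5 had 0 counts in every library.

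Groups followed the tissue and shedding labels, with 6 regions by 2 statuses, or 12 groups of 5. The letter in each title was taken as the animal, since it keeps 1 status over all regions and the labels say that tissues were collected from each animal. As a check, libraries of the same letter were correlated after the group means had been removed. The mean correlation was 0.154 for 150 pairs of the same letter and -0.0271 for other pairs, 92 of the 150 exceeded 0.1, and 22 of 60 libraries had their best match within their letter. By letter the mean ran from -0.00860 (H) and 0.0454 (A) to 0.337 (B), so for H and A the check gives little support. Replicate libraries differed by far more than counting error, with a chi-square per degree of freedom from 43.9 to 11258 over 120 pairs. Depth per sample was the column sum, from 535373 to 19346800 counts. Limits for counts of 0 were set at 3 counts of the library and, like any counting limit, cover counting error only, since the reads carry no molecular identifiers here.

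Comparisons were run in R 4.3.3. Counts were scaled by TMM, filtered with filterByExpr (minimum count 10) and tested with the quasi-likelihood F test of edgeR 4.0.16, with Benjamini-Hochberg adjustment over the miRNAs tested and a threshold of 0.05. The tests are two-sided. Super-shedders were compared with non-shedders in the 10 libraries of each region and in counts summed over the regions of each letter. All 60 libraries in 1 model of 12 group means served for the test of whether the shedding difference varies between regions, for the test of any difference between regions, for the large against the small intestine and for neighbouring regions. Errors of log2 fold changes were taken as the size of the change over the square root of F. Total counts and detected miRNAs were compared by exact permutation tests. Levels are TMM-scaled CPM over all 60 libraries, with the mean and SD.

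Named miRNAs followed a fixed rule. For each shedding comparison they are every miRNA past the threshold, at most 25 by smallest p, and, where fewer than 5 passed, the 5 with the smallest p, given as not passing. For the large against the small intestine they are the 12 largest log2 fold changes in each direction among those past the threshold with a mean of at least 100 CPM, and for neighbouring regions the 5 largest in each direction. Lists of miRNAs were fixed too, for epithelium, muscle, leukocytes, erythroid cells, stroma and endothelium, neural cells, pancreas and liver, the let-7 family, the miR-17-92 family with its paralogs, the HOX clusters, the miR-2284/miR-2285 family and names that match structural RNAs, 12 in all. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, which compares a list with the other miRNAs, adjusted over the lists of a comparison, in 13 comparisons. Alternatives were camera with an estimated correlation and fry, which tests a list on its own.

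The lists, comparisons, tests, named-miRNA rule and most alternatives were set before the data were examined. Alternatives were scaling by size factors (RLE) and to total counts, no low-count filter, a filter at CPM above 5 in at least 5 libraries, a robust dispersion fit, each letter left out in turn, DESeq2 1.42.0, the exact test of edgeR, all 60 libraries in 1 fit, the letter as a block, and limma on means per letter or with the letter as a random block. The letter was a fixed block only in tests between regions, since each letter has 1 status. Chosen after seeing the data were the fits without the 13 libraries outside a marker rule, also with the block, and the list tests under other scalings, with the block and with letters left out. The rule asked for at least 50 CPM of miR-196b in large-intestine libraries and less in small-intestine libraries, at least 10000 CPM of miR-192, and less than 1000 CPM of miR-122. No library was left out of the main results.

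On data simulated from these counts, with 40 changed miRNAs in each of 5 simulations, shedding comparisons within a region recovered from 12.7% to 57.1% of changes of 1 on the log2 scale and from 70.0% to 96.7% of changes of 2. The comparison of the large with the small intestine recovered 94.3% and 100%. Between 1.77% and 5.77% of the calls were false. The simulated libraries were drawn independently, with no animal effect and no outlying library, so these rates hold for such data only. For each count of calls, 100 splits of the samples were compared, the real one included. Shedding splits were drawn from the 126 possible splits of the letters, and region splits shuffled the region labels within each letter. At least 1 miRNA was called in 55 of 100 region splits for any difference between regions, the real one included. For the cecum against the distal jejunum it was 24 of 100, and for a varying shedding difference 49 of 100 shedding splits.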

Results

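Small RNA was sequenced from 60 intestinal tissue libraries of cattle (Bos taurus), and the reads of each library were counted per mature microRNA (miRNA). The libraries came from 6 gut regions, namely duodenum, proximal jejunum, distal jejunum, cecum, spiral colon and descending colon. Each region held 5 libraries from non-shedders, cattle with no Escherichia coli O157 in their feces, and 5 from super-shedders, cattle that excreted large numbers of this bacterium. The sample titles carry a letter, A to E for non-shedders and F to J for super-shedders, and each letter was taken as 1 animal. The p-values for shedding within a region and in the sum over regions rest on that inference. The model of all 60 libraries, behind the main tests between regions and of a varying shedding difference, treats libraries of 1 letter as independent. Total counts ran from 535373 (distal jejunum of letter A) to 19346800 (descending colon of letter A), with a median of 1735050 per library. The regional mean was lowest in the duodenum, at 1701620 ± 707918 (SD, n = 10), and highest in the descending colon, at 5559160 ± 6182380. Between 350 and 507 miRNAs had at least 1 count in a library. Neither total counts (lowest adjusted exact permutation p = 0.714) nor detected miRNAs (0.774) differed between statuses in any of the 6 regions by a two-sided test.

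miR-143, a miRNA of smooth muscle and other mesenchymal cells, supplied 51.8% of all counts and between 8.38% and 70.4% of the counts of single libraries. The epithelial miR-192 supplied 7.80%, miR-10b 6.25%, miR-10a 3.85%, miR-27b 2.76% and miR-26a 2.45%. Levels are read counts over the TMM-scaled size of the library, in the usual unit CPM. A rule set after the values were seen held the markers miR-196b, miR-192 and miR-122 against the region label, and 13 libraries fell outside it, 10 of super-shedders and 3 of non-shedders. By letter and region they are B and I in the proximal jejunum, B, H and I in the distal jejunum, C, H and I in the spiral colon, G, H and I in the descending colon, and I in the duodenum and the cecum. Counts without these 13 libraries stand beside the main counts. Since miR-196b, which differs between regions, put 11 of the 13 outside the rule, more calls between regions without them are partly built in. Those counts are therefore no separate support for the region differences.

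The comparison of super-shedders with non-shedders asks which intestinal miRNAs accompany heavy shedding. With counts summed over the 6 regions of each animal, miR-378b was lower in super-shedders by 14.2-fold, a log2 fold change of -3.83 ± 0.64 (SE, n = 5 animals per status, adjusted p = 0.0282). It was the only one of 361 tested miRNAs to pass, and 34 had an unadjusted p under 0.05. DESeq2 called 7 miRNAs, the exact test of edgeR 3 and limma-voom with the letter as a random block 4, miR-378b among them each time. Limma on means per letter gave 0 calls with 30 at an unadjusted p under 0.05, and there miR-378b was at -3.18 ± 0.64 (adjusted p = 0.144). Letters A to D averaged between 52.3 and 81.2 CPM over their regions, while the non-shedder letter E averaged 4.29 CPM, next to 2.84 to 4.19 CPM in the 5 super-shedders. These means give each region equal weight, while in the tested sums of raw counts a library weighs by its depth. The deepest library of all, the descending colon of letter A, held the lowest level of that letter, 0.848 CPM. The abundant relative of miR-378b, miR-378, encoded in other mammals within the gene of the metabolic coactivator PGC-1β, had a log2 fold change of -0.11 ± 0.15 (adjusted p = 0.842). The next 4 miRNAs by p did not pass in this test. These were miR-2284d (-2.63 ± 0.55, adjusted p = 0.0931) and miR-2284j (-3.13 ± 0.81, 0.173), of a miRNA family found in ruminants, with miR-2285k of the same family (0.82 ± 0.20, 0.144) and miR-423-5p (-0.88 ± 0.21, 0.144). All 4 passed in DESeq2 (6.32e-04, 0.00963, 0.00670 and 0.0181), miR-2284d also in the exact test (8.92e-04), and miR-2284j in the exact test (0.0386) and limma-voom (0.00458). Near-identical copies make the split of reads within the miR-378 and miR-2284/miR-2285 families uncertain. The call for miR-378b was lost without letter B (adjusted p = 0.0894), C (0.0760), D (0.0835), G (0.0899), H (0.127), I (0.0668) or J (0.0672), held without A (0.0382) or F (0.0487), and held without E (-4.10 ± 0.36, 1.11e-04). Without E miR-2284d also passed (0.00435), and without F so did miR-2285k (0.0487). Without the 13 libraries outside the marker rule 0 miRNAs passed in edgeR and 31 had an unadjusted p under 0.05, with miR-378b at -3.64 ± 0.70 (0.0793).

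Region by region, miR-378b was lower in super-shedders in the duodenum, the distal jejunum and the spiral colon. Its log2 fold change was -4.27 ± 0.75 (SE, n = 5 per status, adjusted p = 0.0275) in the duodenum, -3.77 ± 0.66 (0.0296) in the distal jejunum and -3.94 ± 0.64 (0.0169) in the spiral colon. In the duodenum it averaged 55.4 ± 31.7 CPM (SD, n = 5) in non-shedders and 2.78 ± 1.98 CPM in super-shedders. It did not pass in the cecum (-3.90 ± 0.73, adjusted p = 0.0517; 4.61e-05 by the exact test of edgeR) or the descending colon (-3.27 ± 1.03, 0.979). In the proximal jejunum the low-count filter removed it, and with no filter it was at -4.42 ± 0.69 (0.00963). The descending colon library of letter A held 0.848 CPM of miR-378b, far below the other 5 libraries of that letter. In the duodenum the call was lost without any of letters A to D or F to J (adjusted p from 0.0581 to 0.149) and kept without E (7.13e-04), and in the distal jejunum likewise (0.0540 to 0.130, and 2.84e-04 without E). In the spiral colon it was lost without B (0.0518), G (0.0831), H (0.0704), I (0.0628) or J (0.0764). Without letter E miR-378b also passed in the cecum (4.80e-04) and the proximal jejunum (5.14e-05), and without the 13 libraries it passed in none of these regions (duodenum 0.0660, distal jejunum 0.455, cecum 0.106, spiral colon 0.424). That left 9 libraries in the duodenum, 7 in the distal jejunum, 9 in the cecum and 7 in the spiral colon. Lost power cannot be told apart there from a dependence on the libraries left out.

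**Figure D1:**
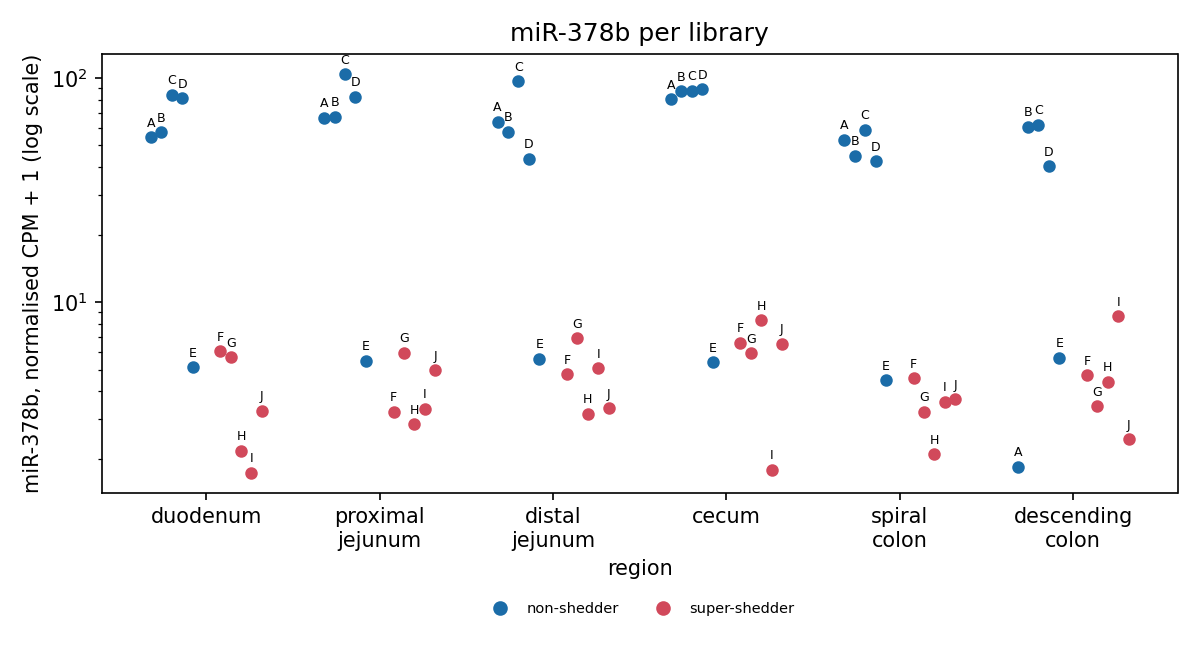
Level of miR-378b in each of the 60 libraries, as CPM plus 1 on a log axis, by gut region, with non-shedders in blue, super-shedders in red and the letter of the animal beside each point. Non-shedder letters A to D average 52.3 to 81.2 CPM over their regions, and letter E (4.29 CPM) lies with the 5 super-shedders (2.84 to 4.19 CPM).

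Other miRNAs with small p-values differed from region to region and did not pass in the edgeR fit of each region. With all 60 libraries in 1 fit 3 passed in each of the duodenum, the proximal and the distal jejunum, 2 in the descending colon, and 1 in the cecum and in the spiral colon, miR-378b among them each time. In the duodenum, among 239 tested miRNAs (9 with an unadjusted p under 0.05), these were miR-2285k (0.98 ± 0.27, adjusted p = 0.453), miR-409a, miR-99a-5p and miR-1271, and all 60 libraries in 1 fit added miR-122 (11.41 ± 1.96) and miR-30a-5p (1.55 ± 0.42, 0.0493). Both rest on the library of letter I, with 9635 and 66344 CPM against at most 10.1 and 9113 CPM in the other 9. The proximal jejunum (237 tested) gave 0 calls in edgeR with 24 at an unadjusted p under 0.05, 0 by its exact test and 1 by DESeq2. Without the 13 libraries edgeR gave 0 calls there with 21 at an unadjusted p under 0.05. Its smallest p-values belonged to miR-362-5p (1.63 ± 0.45), miR-874 (1.68 ± 0.49), miR-32 (-1.05 ± 0.31), miR-185 (0.93 ± 0.30) and miR-10a (1.73 ± 0.55), each at an adjusted p of 0.352, and miR-362-5p (0.0304) and miR-99a-5p (0.0491) passed with all 60 libraries, the latter with 16969 CPM in the library of letter I and at most 810 CPM in the other 9. In the distal jejunum (243 tested, 24 with an unadjusted p under 0.05), miR-6123 stood at -1.14 ± 0.28 (0.215), followed by miR-18a (-1.59 ± 0.44), miR-296-3p and miR-379. There DESeq2 gave 4 calls, miR-18a (0.0249) among them, and all 60 libraries in 1 fit called miR-296-3p (0.00978) and miR-2284j (0.0211) as well. The cecum (260 tested) gave 0 calls in edgeR with 16 at an unadjusted p under 0.05, 1 by the exact test and 2 by DESeq2, and without the 13 libraries 0 in edgeR with 27 at an unadjusted p under 0.05. There miR-320a (-0.68 ± 0.17), let-7d (-0.80 ± 0.23), let-7e (-1.13 ± 0.32) and miR-423-5p (-1.28 ± 0.37) followed miR-378b, each at an adjusted p of 0.242. In the spiral colon (261 tested, 19 with an unadjusted p under 0.05) miR-451, a miRNA of red blood cells, had a log2 fold change of -1.77 ± 0.42 (0.190), and it passed without letter D (0.00928), by DESeq2 (0.00752) and by the exact test (0.0110), followed by miR-92b, miR-193a-3p and miR-23b-3p. The descending colon (269 tested) gave 0 calls in edgeR, its exact test and DESeq2, with 8, 12 and 15 miRNAs at an unadjusted p under 0.05. All 60 libraries in 1 fit gave 2 calls there, miR-486 (3.46 ± 0.70, adjusted p = 0.00221) and miR-378b (0.0354), and without the 13 libraries, with F and J the only super-shedders left, edgeR gave 0 with 1 at an unadjusted p under 0.05. Its red blood cell miRNAs miR-486 (3.50 ± 1.24) and miR-451 (2.62 ± 0.99), then miR-99a-5p and miR-1343-3p, were at an adjusted p of 0.979 in the fit of the region alone, and the library of letter I alone held 17787 CPM of miR-486 against at most 637 CPM in the other 9. Over the 6 regions miR-2285k was higher in super-shedders in 6 of 6, with log2 fold changes from 0.67 to 1.08. Among the named miRNAs so were miR-409a, miR-99a-5p, miR-1271, miR-185, miR-379 and miR-1343-3p, while miR-320a, let-7d and miR-423-5p were lower in 6 of 6. The regions came from the same animals, so this agreement is not independent from region to region.

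In the fixed lists of related miRNAs, 0 members passed over all tested miRNAs in any of the shedding comparisons. The bovine miR-2284/miR-2285 family leaned higher in super-shedders in the duodenum, where 8 of 9 tested members were positive and 1 passed adjusted over the list alone (camera adjusted p = 0.00793, and adjusted p = 0.0900 with an estimated correlation). Of the positive members, miR-2284x (0.0313) and miR-2284y (0.0305) had nearly the same values and may count the same reads. The family leaned the same way in the proximal jejunum (camera 0.0250, adjusted p = 0.570 with an estimated correlation), a call lost without C (0.0570), G (0.121) or J (0.0811). In the cecum (0.0111, adjusted p = 0.382 with an estimated correlation) the call was lost without A (0.0658), F (0.148), H (0.294) or I (0.0537). In the descending colon (0.0267, adjusted p = 0.471 with an estimated correlation) it was lost without A (0.139), C (0.102), F (0.0865), G (0.0819), H (0.287), I (0.0858) or J (0.0725), and without the 13 libraries, with F and J the only super-shedders left, the median turned from 0.22 to -0.11. Over all regions (0.0332, adjusted p = 0.766 with an estimated correlation) it was lost without F (0.0515). There 3 members were higher and 2 lower adjusted over the list alone, the lower ones being miR-2284d and miR-2284j. Scaling to total counts ended the calls in the proximal jejunum (0.0585), the descending colon (0.0653) and all regions (0.123).

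Lists that mark cell types gave camera calls in some regions, none of which held with an estimated correlation, and whether a list differed between regions in its shedding difference was not tested. In the proximal jejunum the epithelium list was lower in super-shedders (camera adjusted p = 6.99e-04, and adjusted p = 0.570 with an estimated correlation), with 0.0706 without the 13 libraries. Letter I held 3086 CPM of epithelial miRNAs there against at least 51037 CPM in the other 9 libraries. The stroma and endothelium list was higher (0.0250, adjusted p = 0.570 with an estimated correlation), a call lost without letter I (0.623), whose library held 125092 CPM of its members. The miR-17-92 family, whose miRNAs accompany cell proliferation, was lower (0.0250, adjusted p = 0.570 with an estimated correlation), a call lost without I (0.648) or J (0.0595) and with scaling to total counts (0.113). In the distal jejunum the same family was lower (3.00e-06, adjusted p = 0.546 with an estimated correlation, and 0.0658 without the 13 libraries), with 1 member lower adjusted over the list alone.

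In the cecum the epithelium list was higher in super-shedders (camera adjusted p = 2.69e-04, and adjusted p = 0.431 with an estimated correlation), a call lost without the non-shedder letter E (0.0723), whose cecum held the least, 28710 CPM. The muscle list was lower (0.0140, adjusted p = 0.440 with an estimated correlation), a call lost without B (0.0512), E (0.0923) or F (0.148). The let-7 family was lower with a median of -0.23 that turned to 0.15 with scaling to total counts (0.00736, adjusted p = 0.382 with an estimated correlation), and 2 members were lower adjusted over the list alone. Its call was lost without H (0.0578). The leukocyte list was higher (0.0334, adjusted p = 0.506 with an estimated correlation), a call lost without D (0.0792), E (0.367), F (0.148), G (0.0958), H (0.183) or J (0.101).

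In the descending colon the epithelium list was lower in super-shedders (camera adjusted p = 1.93e-04, and adjusted p = 0.471 with an estimated correlation), a call lost without letter I (0.0858), whose library held 3646 CPM against at least 38755 CPM in the other 9. The erythroid list was higher (0.0267, adjusted p = 0.471 with an estimated correlation), with 3 members higher adjusted over the list alone and the call lost without C (0.102) or I (0.332). The HOX-cluster miRNAs were lower with a median of -0.42 (0.0267, adjusted p = 0.471 with an estimated correlation). The median turned to 0.16 without the 13 libraries, which left 7 libraries there, with F and J the only super-shedders. The call of this list was lost without B (0.0608), C (0.102), G (0.181), H (0.270) or J (0.0725), and the libraries of G and H held 1.22 and 0 CPM of miR-196b. A count of 0 in the library of H allows a level of up to 1.71 CPM.

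The spiral colon had 0 list calls by camera in limma, with 0 by fry, and there 1 erythroid member was lower and 1 miR-17-92 member higher adjusted over the list alone. Neural miRNAs gave no call in any shedding comparison. The pancreas and liver list (miR-122) could not be tested as a list, and miR-122 itself had a log2 fold change of 6.55 ± 2.40 over all regions (edgeR adjusted p = 0.311, unadjusted p = 0.0190), which rests on the duodenum of letter I. As the only tested member of its list it has no separate adjustment over the list alone. The structural RNA list, names whose sequences match abundant structural RNAs, was tested in the sum over regions and gave no call.

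Whether the shedding difference itself changed from region to region was tested with 1 model of all 60 libraries. Of 288 miRNAs, miR-122, the main miRNA of hepatocytes, passed (adjusted p = 0.0108), and 15 had an unadjusted p under 0.05. It averaged 1929 ± 4307 CPM (SD, n = 5) in the duodenum of super-shedders and 0.643 ± 0.486 CPM in that of non-shedders. The library of letter I held 9635 CPM and the other 59 libraries at most 44 CPM. The call was lost without A (0.0782), B (0.433), C (0.107), D (0.169) or E (0.138), and without letter I, where 0 miRNAs passed in edgeR and 12 had an unadjusted p under 0.05. It was also lost with the letter as a block (0.939) and without the 13 libraries (0.997), where edgeR gave 0 calls in each case and 11 miRNAs had an unadjusted p under 0.05. Without G, miR-451 and miR-486 passed too (both 0.0430). Between regions the status difference of miR-378b did not pass as different (adjusted p = 0.992).

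The regions themselves differed in 63 of 288 miRNAs (114 with an unadjusted p under 0.05), by a test of all 6 regional means. The count was 40 without letter J, 123 without letter I, 39 with scaling to total counts and 164 without the 13 libraries, of which 58 were among the 63.

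Between the large intestine (cecum, spiral and descending colon) and the small intestine, the sharpest difference was in miRNAs encoded within the HOX gene clusters, which pattern the body axis. miR-196b was higher in the large intestine by a log2 fold change of 4.74 ± 0.78 (SE, 30 libraries per side, adjusted p = 1.62e-05) and miR-196a by 4.08 ± 0.53 (1.43e-07). miR-196a averaged 173.4 ± 122.1 CPM (SD, n = 30) in the large and 35.9 ± 70.0 CPM in the small intestine. miR-10b (1.64 ± 0.30) and miR-10a (1.49 ± 0.26) rose with them. On the other side, miR-215, an epithelial relative of miR-192, fell by 2.03 ± 0.40 on the log2 scale (1.20e-04), from 23252 ± 14676 CPM to 8257 ± 10533 CPM. miR-146a, a brake on inflammatory signalling, fell by 1.05 ± 0.22 (3.09e-04), the blood cell miRNA miR-142-3p by 0.78 ± 0.27 (0.0260) and miR-155, a miRNA of activated lymphocytes, by 0.55 ± 0.19 (0.0250). Of 288 tested miRNAs 34 were higher and 44 lower in the large intestine, 19 of them by over 2-fold, and 120 had an unadjusted p under 0.05. Scaling to total counts, which shifted the median of all miRNAs to -0.22 on the log2 scale, gave 17 higher and 67 lower. With the letter as a block on counts summed per letter, which holds fewer samples, 46 passed. Without the 13 libraries 159 miRNAs passed, 74 higher and 85 lower, among them 75 of the 78, and without letter I 128 passed. The marker rule drops libraries whose miR-196b ran against this comparison, so the rise to 159 is partly built in. miR-142-3p lost its call without D (0.0601), E (0.116) or F (0.0886), and miR-155 without E (0.0737), F (0.0651), G (0.0851) or J (0.103).

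**Figure D2:**
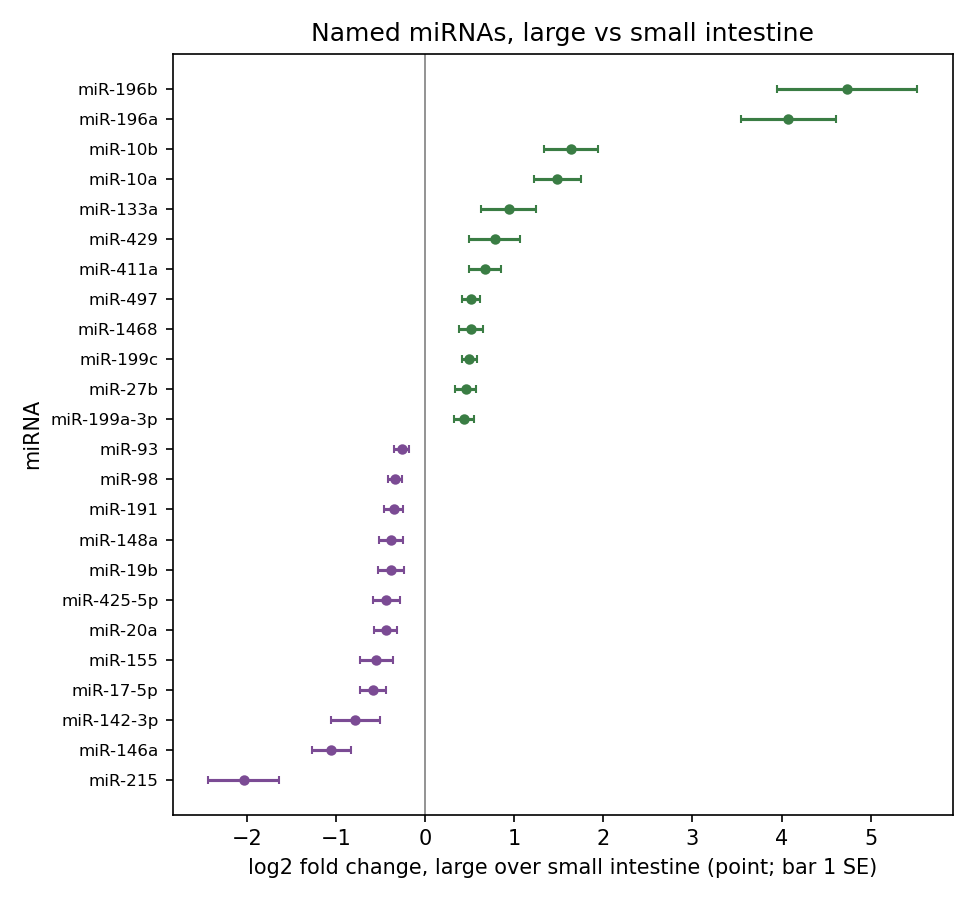
Log2 fold change of the large over the small intestine for the 12 most increased and 12 most decreased miRNAs among those that passed with a mean of at least 100 CPM, from all 60 libraries, with bars of 1 SE. The HOX-cluster miRNAs miR-196b (4.74), miR-196a (4.08), miR-10b (1.64) and miR-10a (1.49) lead the increases and miR-215 (-2.03) the decreases.

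Among other abundant miRNAs, the muscle miRNA miR-133a (0.94 ± 0.31, adjusted p = 0.0189), the epithelial miR-429 (0.78 ± 0.28, 0.0337), miR-411a (0.68 ± 0.18, 0.00300), miR-497 (0.52 ± 0.10), miR-1468 (0.51 ± 0.14), miR-199c (0.50 ± 0.09), miR-27b (0.45 ± 0.11) and miR-199a-3p (0.44 ± 0.11) were higher in the large intestine. miR-17-5p (-0.59 ± 0.14), miR-20a (-0.44 ± 0.13), miR-425-5p (-0.43 ± 0.15), miR-19b (-0.38 ± 0.15), miR-148a (-0.38 ± 0.14), miR-191 (-0.35 ± 0.10), miR-98 (-0.34 ± 0.08) and miR-93 (-0.26 ± 0.09) were lower. miR-429 held its call only with all letters or without I (otherwise 0.0510 to 0.0941), and miR-133a lost it without E (0.0737), F (0.110), G (0.0619) or J (0.0817). Among the lower ones, miR-425-5p lost its call without E (0.0675), F (0.0515) or G (0.0929), miR-19b without D (0.103), E (0.217), F (0.175) or G (0.0851) and with the letter as a block (0.0515), miR-148a without C (0.0525), E (0.0603) or F (0.104), and miR-93 without G (0.0515). Without the 13 libraries miR-1468 (0.0627) and miR-148a (0.0555) did not pass, and with scaling to total counts miR-429, miR-497, miR-1468, miR-199c and miR-199a-3p did not (0.196 to 0.357).

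By list, all 4 tested HOX-cluster miRNAs rose in the large intestine, as they did adjusted over the list alone, and camera called the list (adjusted p = 7.44e-06, adjusted p = 0.0355 with an estimated correlation). Of 13 members of the miR-17-92 family, whose miRNAs accompany cell proliferation, 9 fell and 4 did not pass, with 10 lower adjusted over the list alone. Examples are miR-20b (-1.82 ± 0.35), miR-106a (-1.35 ± 0.33) and miR-18a (-0.75 ± 0.21). Camera called it (1.37e-04), with an adjusted p = 0.313 with an estimated correlation. Of 13 members of the miR-2284/miR-2285 family 5 fell, among them miR-2285p (-1.08 ± 0.28) and miR-2285k (-0.72 ± 0.19), and 8 did not pass, with 5 lower adjusted over the list alone (camera 0.00711, adjusted p = 0.101 with an estimated correlation).

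Of 13 leukocyte miRNAs 4 fell (miR-142-3p, miR-146a, miR-155 and miR-363, -1.06 ± 0.26), miR-147 rose (1.14 ± 0.28) and 8 did not pass, with 6 lower and 1 higher adjusted over the list alone. Its camera adjusted p was 0.0438 (adjusted p = 0.616 with an estimated correlation), and the call was lost with scaling to total counts (0.10) and without A (0.0595), E (0.101), F (0.0676), G (0.0930) or J (0.0595). Of 14 stroma and endothelium miRNAs miR-497 and miR-199a-3p rose, 2 rose adjusted over the list alone, and 12 did not pass. Its camera adjusted p was 0.0489 (adjusted p = 0.511 with an estimated correlation), lost with scaling to total counts (0.236), without the 13 libraries (0.0837) and without A (0.0595), C (0.0662), E (0.0596), G (0.108) or I (0.0541). Letter I held 25649 CPM of the stromal miR-100 in its descending colon library, where the highest of the other 9 held 6159 CPM, and 67017 CPM in its proximal jejunum library, where the highest held 5515 CPM.

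The remaining lists gave no camera call. Of 12 epithelial miRNAs miR-429 rose and miR-215 fell, with 1 lower adjusted over the list alone, and 10 did not pass (median 0.17, or -0.07 with scaling to total counts). Of 6 muscle miRNAs miR-133a and miR-499 (0.51 ± 0.18) rose and 4 did not pass, with 2 higher adjusted over the list alone. Of 10 neural miRNAs miR-138 fell (-0.86 ± 0.31), 9 did not pass, and 0 passed adjusted over the list alone. Of 10 let-7 miRNAs miR-98 fell, also adjusted over the list alone, and 9 did not pass. None of the 3 erythroid miRNAs passed, by either adjustment (median 0.20, or -0.12 with scaling to total counts). In the pancreas and liver list only miR-122 was tested (-3.19 ± 1.26, adjusted p = 0.0519, and unadjusted p = 0.0144, which an adjustment over this list of 1 leaves unchanged), with 9635 CPM in the duodenum of letter I. In the structural RNA list only miR-2904 was tested (0.22 ± 0.32, 0.646).

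Entering the jejunum from the duodenum, miR-10a rose by a log2 fold change of 3.67 ± 0.49 (SE, n = 10 libraries per region, adjusted p = 2.50e-07), from 2573 ± 1882 CPM (SD, n = 10) to 38865 ± 47742 CPM. miR-196a (5.77 ± 1.14, 3.12e-04) rose with it, and so did miR-181b (0.92 ± 0.18) and miR-181a (0.90 ± 0.19), which are abundant in lymphocytes and neurons. miR-148a, abundant in secretory and liver cells, fell by 1.55 ± 0.24 (5.16e-06), from 48685 ± 24620 CPM to 16540 ± 6520 CPM, and miR-186 (-0.35 ± 0.09) was also lower. miR-196b passed as well (5.50 ± 1.53, 0.0161), but the proximal jejunum libraries of letters B and I held 167 and 316 CPM of it and the other 8 at most 7.49 CPM. Its call was lost without B (0.349) or I (0.163), with the letter as a block (0.150) and without the 13 libraries (1.13, 0.227). miR-101 (-0.79 ± 0.23, 0.0208) lost its call without A (0.0611), B (0.0678), C (0.0813), D (0.137) or I (0.196), with the block (0.0604) and without the 13 libraries (0.228), and miR-186 without B (0.0556), C (0.0756) or D (0.0506). Scaling to total counts ended the calls of miR-101 (0.0680), miR-181a (0.0840) and miR-186 (0.515). In all, 14 miRNAs were higher and 5 lower (61 with an unadjusted p under 0.05). The count of 19 became 42 without letter I, 12 without B, 12 without D, 11 with scaling to total counts, and 57 without the 13 libraries, of which 17 were among the 19.

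The HOX-cluster list rose at this border in 3 of 4 members (4 adjusted over the list alone; camera adjusted p = 3.65e-04, adjusted p = 0.143 with an estimated correlation). The neural list was higher (0.0109, adjusted p = 0.331 with an estimated correlation), with miR-138 (2.09 ± 0.55), miR-132 (1.34 ± 0.39) and miR-129-3p (1.47 ± 0.48) up and miR-153 (-2.27 ± 0.49) down among 10, and 6 up and 1 down adjusted over the list alone. The leukocyte list was higher (0.0237, adjusted p = 0.663 with an estimated correlation, 0.0730 with scaling to total counts, lost without E at 0.0553, or J at 0.0899), with miR-181a and miR-181b up among 13, and 2 up adjusted over the list alone. The epithelium list was lower (0.00235, adjusted p = 0.663 with an estimated correlation), with 0 of 12 members past the threshold and miR-141 and miR-375 lower adjusted over the list alone.

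From the distal jejunum to the cecum miR-215 fell by 3.94 ± 0.75 on the log2 scale (SE, n = 10 libraries per region, adjusted p = 7.33e-04), from 17916 ± 11905 CPM (SD, n = 10) to 1165 ± 451 CPM. miR-146a fell by 1.68 ± 0.39 (0.00314), from 1904 ± 973 CPM to 601 ± 231 CPM, and miR-181b (-0.65 ± 0.18) and miR-181a (-0.58 ± 0.19, 0.0497) were lower as well. miR-411a, of the large imprinted cluster around miR-379, was higher by 1.11 ± 0.31 (0.0174), and miR-22-3p by 0.70 ± 0.21 (0.0227). In all, 16 miRNAs were higher and 9 lower (78 with an unadjusted p under 0.05). miR-411a lost its call without A (0.0542), E (0.0989) or J (0.0770), miR-22-3p without A (0.0705), E (0.114), F (0.0806) or J (0.0546), and miR-181a without A (0.0913), B (0.0696), D (0.0582), F (0.0880), G (0.0596) or J (0.0546). Scaling to total counts ended the calls of miR-411a (0.95, adjusted p = 0.0522), miR-22-3p (0.49, 0.330), miR-181b (-0.93, 0.0683) and miR-181a (-0.89, 0.0895). miR-181a also lost its call with robust dispersion (0.0501) and with no low-count filter (0.137). The count of 25 was 46 with the letter as a block, 4 (1 higher, 3 lower) with scaling to total counts, 15 without letter A, 16 without E, 58 without I, and 89 without the 13 libraries, of which 24 were among the 25. The distal jejunum libraries of B, H and I held 214, 792 and 894 CPM of miR-196b, a marker of the large intestine, and the other 7 at most 3.92 CPM.

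In the leukocyte list 4 of 13 members fell and miR-147 rose (2.18 ± 0.50), with 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00435, adjusted p = 0.306 with an estimated correlation). In the miR-17-92 family miR-20b fell (-2.23 ± 0.60), and 6 of 13 fell adjusted over the list alone (4.63e-04, adjusted p = 0.306 with an estimated correlation). In the miR-2284/miR-2285 family miR-2285k fell (-1.19 ± 0.33), and 2 of 13 fell adjusted over the list alone (0.00905, adjusted p = 0.233 with an estimated correlation, 0.0780 without the 13 libraries). Of 10 neural miRNAs 0 passed by either adjustment, and the list was lower (0.0366, adjusted p = 0.306 with an estimated correlation, 0.0780 without the 13 libraries, lost without A at 0.0802, C at 0.0665, H at 0.0746, or J at 0.0627). Of 4 HOX-cluster miRNAs 0 passed by either adjustment. That list was higher (0.0366, adjusted p = 0.306 with an estimated correlation), and the call was lost with the letter as a block (0.0575) and without A (0.0560), C (0.0665), F (0.106), G (0.0925) or J (0.0759).

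**Figure D3:**
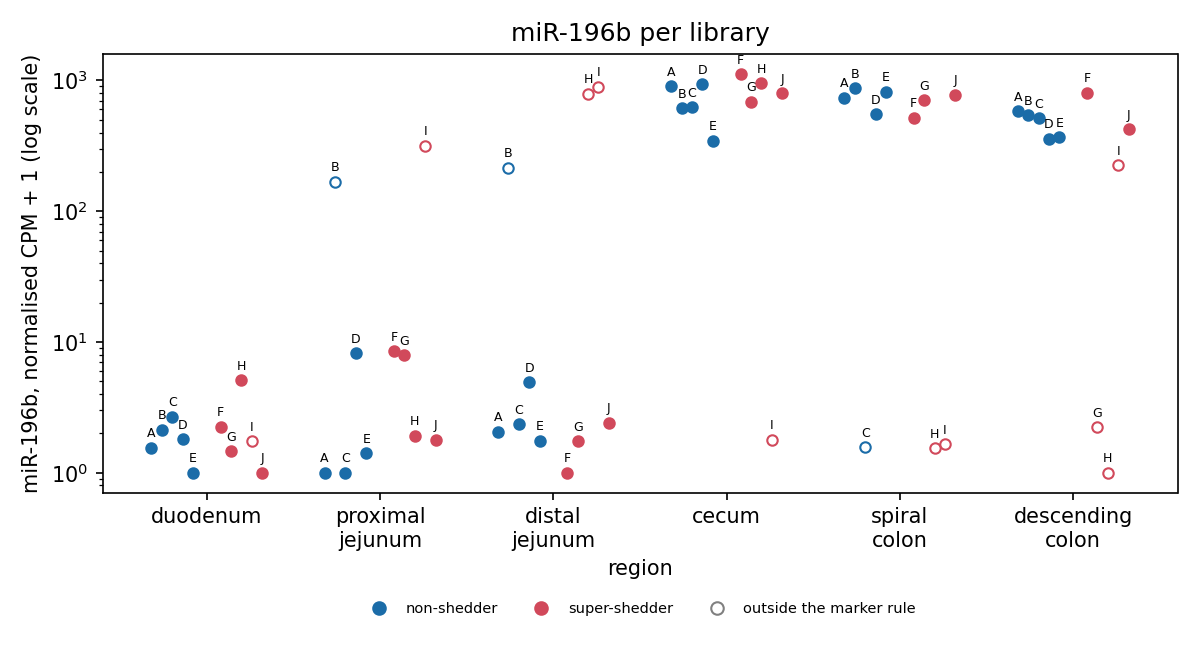
Level of miR-196b in each of the 60 libraries, as CPM plus 1 on a log axis, by gut region, with non-shedders in blue, super-shedders in red, the letter beside each point and hollow points for the 13 libraries outside the marker rule. The cecum averages 699 ± 329 CPM and the duodenum 1.08 ± 1.19 CPM (SD, n = 10), while the cecum library of letter I holds 0.794 CPM.

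Between the other neighbouring regions few or 0 miRNAs passed in the main tests, which does not show equal levels. Past the cecum, miR-215 rose again in the spiral colon by a log2 fold change of 3.04 ± 0.72 (SE, n = 10 libraries per region, adjusted p = 0.0259), to 9572 ± 9278 CPM (SD, n = 10), and it was the only miRNA to pass (22 with an unadjusted p under 0.05). It lost its call without B (0.0707), C (0.202), F (0.0632) or H (0.0898). Without letter B, C or H the only call was instead miR-6526, and without F there were 0 calls in edgeR, with 21 at an unadjusted p under 0.05. Without A, D, E, G or J there were 2 calls (miR-215 and miR-6526), and without I there were 3. Scaling to total counts gave 0 calls, with 15 at an unadjusted p under 0.05, and leaving out the 13 libraries gave 5 (miR-215 at 1.92 ± 0.45, adjusted p = 0.0165). Between spiral colon and cecum the neural list was higher (camera adjusted p = 4.90e-04, adjusted p = 0.119 with an estimated correlation, 1 of 10 up adjusted over the list alone). So were the leukocyte list (0.0173, adjusted p = 0.460 with an estimated correlation, lost without C at 0.0866, E at 0.0676, or I at 0.302) and the miR-2284/miR-2285 family (0.0173, adjusted p = 0.170 with an estimated correlation, lost without A at 0.0945, or I at 0.297). With the letter as a block the let-7 family was called as well (0.0489).

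The distal and the proximal jejunum differed in 0 miRNAs in edgeR, with 5 at an unadjusted p under 0.05, and without the 13 libraries in 0 with 6. The HOX-cluster list was higher in the distal jejunum (camera adjusted p = 0.0206, adjusted p = 0.656 with an estimated correlation), with 0 of 4 members past the threshold. That call was lost without the 13 libraries (0.712) and without A (0.0962), C (0.0723), D (0.219), E (0.0799), H (0.297), I (0.178) or J (0.0643). The descending and the spiral colon differed in 0 miRNAs in edgeR, with 15 at an unadjusted p under 0.05 and the smallest adjusted p at 0.0625, and without the 13 libraries in 0 with 20. miR-486 passed there without G (2.07 ± 0.49, 0.0301), H (0.0408) or J (0.0367).

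Between these 2 regions of the colon 7 lists were called, and 0 list members passed. The erythroid list was higher in the descending colon (camera adjusted p = 0.010, adjusted p = 0.257 with an estimated correlation, 3 higher adjusted over the list alone, lost without D at 0.0740, or I at 0.293), with 19052 CPM of its members in the library of letter I against at most 701 CPM in the other 9. The stroma and endothelium list was higher too (0.0323, adjusted p = 0.379 with an estimated correlation, lost without C at 0.0966, D at 0.109, or I at 0.400). The epithelium list (0.00505, adjusted p = 0.385 with an estimated correlation, lost without I at 0.189), the leukocyte list (0.00743, adjusted p = 0.379 with an estimated correlation, lost without I at 0.189) and the neural list (0.010, adjusted p = 0.257 with an estimated correlation, lost without D at 0.101, or I at 0.189) were lower. So were the miR-17-92 family (0.0474, adjusted p = 0.494 with an estimated correlation, lost with the letter as a block, 0.0654, and without C, 0.487, F, 0.363, or I, 0.337) and the miR-2284/miR-2285 family (0.00631, adjusted p = 0.150 with an estimated correlation). Of the 41 camera calls over all comparisons, 1 held with an estimated correlation, that of the HOX-cluster miRNAs in the large intestine.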

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

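The tests of explanations in this part, and the measures screened for libraries far from the rest of their group, were chosen after the results were seen. In 107 groups of 5 libraries, the gap of the highest or lowest library to its neighbour was set against the whole range of the group, and "next" below is the neighbour within the same region and status. Levels in CPM entered as the log of CPM plus 1, so the gaps do not follow from the printed CPM directly. In 18 groups the gap over the range exceeded the 95% limit of 0.71, where chance gives about 1 in 20, and 7 of the 18 belonged to letter I.

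In 5 regions the non-shedder letter E was far below the other 4 non-shedders in miR-378b, at 4.14 CPM in the duodenum (next 53.3), 4.47 in the proximal jejunum (next 65.4), 4.59 in the distal jejunum (next 42.6), 4.4 in the cecum (next 79.4) and 3.50 in the spiral colon (next 41.4). A fixed share of miR-378 reads counted as miR-378b is argued against as the source of the lower miR-378b in super-shedders, since miR-378 had a log2 fold change of -0.11 ± 0.15 where miR-378b had -3.83 ± 0.64, but a change in that share stays open, since it would not show in miR-378 at a mean of 4605 CPM. A lasting difference between animals apart from shedding may contribute, since letters of the same status differed in miR-378b (adjusted p = 6.02e-06 in edgeR). A sequence variant near the miR-378b gene cannot be told apart from it without the reads: miR-2284j, encoded on the same chromosome with 10 genes between, had a log2 fold change of -3.13 ± 0.81 (adjusted p = 0.173), with 4.06 to 5.74 CPM in letters A to D and 0 to 1.08 CPM in E to J. Shedding status stays open as the biological explanation and was not tested apart from the animal, since each animal has 1 status.

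miR-196b ran against the region label in 11 libraries, the farthest from their groups being the cecum of letter I (0.794 CPM, next 688), the spiral colon of letter C (0.564 CPM, next 550) and the distal jejunum of letter B (214 CPM, next 3.92). Loss of miR-196b reads alone in the large-intestine libraries is argued against, because in 6 of 6 such libraries miR-196a, at most 24.7 CPM, lay below the 50.1 CPM or more of the large-intestine libraries within the marker rule (the descending colon of letter I, outside it by miR-192, held 7.63 CPM). Little epithelium in the large-intestine libraries is argued against too, because in 6 of 6 the epithelium sum, from 92745 to 251296 CPM, lay above the lowest within the marker rule, 28710 CPM. Tissue of the small intestine under a colon label is a candidate explanation in the spiral colon of C, H and I and the descending colon of G and H, since 5 of 5 lay at -0.873 to -0.242 on a score of 104 other miRNAs that put 1 of its 30 training libraries on the wrong side, and the 23 large-intestine libraries within the rule at 0.0453 or more. Tissue of the small intestine under a cecum label stays open with 0 of 1 library on that side (0.693), since 1 library decides little. Tissue of the large intestine under a small-intestine label stays open too, with 3 of 5 libraries on the large-intestine side and those of letter B not. Among the 3 are the proximal (1.27) and distal jejunum (0.787) of letter I, which held little epithelium. The duodenum of letter I also lay on that side (0.364). Whether the score follows epithelium was not tested, and no biological explanation was tested.

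Letter I held few epithelial miRNAs in 3 libraries: the epithelium sum was 6820 CPM in the distal jejunum (next 83718), the stroma and endothelium sum 125092 CPM in the proximal jejunum (next 19486), and the erythroid sum 519 CPM in the distal jejunum (next 356, but 848 CPM in a non-shedder) and 19052 CPM in the descending colon (next 486, and at most 701 CPM in the other 9). Muscle layer with little mucosa is a candidate explanation in the jejunum, where in 2 of 2 libraries the muscle sum, 1190370 and 1511000 CPM, exceeded the highest of the other 9 (486962 and 732178 CPM) and miR-192 was at 2679 and 5807 CPM against at least 41723 and 57597 CPM. The sums are TMM-scaled and can exceed the total of a library, so they are not shares of counts. Shares of raw counts are not given for the muscle list. In the descending colon muscle layer with little mucosa is argued against on these scaled sums only, since 6 of the other 9 libraries had a higher muscle sum than the 424350 CPM of letter I. Blood diluting the descending colon library is argued against as the reason for its low epithelium, since erythroid miRNAs made up 1.49% of its raw counts. What lowered the epithelium there stays open, and no biological explanation was tested, since the 3 libraries share 1 letter.

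The remaining libraries far from their groups are given as values. In the cecum of super-shedders miR-378b was lowest in letter I, at 0.794 CPM (next 4.91). The epithelium sum was lowest in letter E among the cecum libraries of non-shedders, at 28710 CPM (next 91786). The muscle sum was lowest in letter A among the distal jejunum libraries of non-shedders, at 150810 CPM (next 338069), and in letter D among their descending colon libraries, at 57282 CPM (next 798265). In the descending colon of super-shedders letter J had the most miRNAs with at least 1 count, 495 (next 390). In the duodenum of super-shedders letter I held 9635 CPM of miR-122 (next 10.1). The shedding difference of miR-122 varied between regions by the test of that difference itself (adjusted p = 0.0108), and without letter I 0 miRNAs passed it in edgeR, with 12 at an unadjusted p under 0.05.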

How the results depend on the processing

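Fits without the 13 libraries outside the marker rule, with or without the block, and the list tests under other scalings, with the block and with letters left out were chosen after seeing the data. For every change given here the cause was not tested, except where fewer miRNAs or libraries in the fit are named. Among named miRNAs 0 of 740 values with a direction changed it with a letter left out and 0 of 645 under other settings. These miRNAs were named for small p or large change in the same counts, so a kept direction was likely and is no separate support. Of 839 and 725 values, the test of a varying shedding difference included, 93 and 56 lost their call, and 6 and 19 gained one. Depth and detected miRNAs gave 0 calls with a floor of 1 or 10 counts. With few libraries, changes near 1 on the log2 scale were often missed in the simulated shedding comparisons, so that missing calls there do not show equal levels. Beyond the counts listed here, the block changed the calls of miR-19b, miR-101, miR-196b and miR-122 and of 3 lists, which stand beside those results, and no other named call.

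Counts of called miRNAs for super-shedders against non-shedders moved as follows. In the duodenum (1) they were 0 without the 13 libraries and 3 with all 60 libraries in 1 fit. In the proximal jejunum (0) they were 1 with no low-count filter, 1 with the filter at CPM above 5, 1 with DESeq2 and 3 with all 60 libraries. In the distal jejunum (1) they were 0 without the 13 libraries, 4 with DESeq2 and 3 with all 60 libraries. In the cecum (0) they were 1 with RLE size factors, 1 with no filter, 2 with DESeq2, 1 with the exact test and 1 with all 60 libraries. In the spiral colon (1) they were 0 with the CPM filter, which removes miR-378b, 0 without the 13 libraries, 2 with DESeq2 and 2 with the exact test. In the descending colon (0) they were 2 with all 60 libraries. Over all regions (1) they were 0 with the CPM filter, 0 without the 13 libraries, 7 with DESeq2, 3 with the exact test, 0 with limma on means per letter and 4 with limma-voom and a random block. The test of a varying shedding difference (1) gave 0 with the block, 0 without the 13 libraries and 0 with both.

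Between regions, the count of any difference (63) was 39 with total counts, 164 without the 13 libraries and 173 with the block as well. For the large against the small intestine (78) it was 159 without the 13 libraries, 170 with the block as well and 46 with the block on counts summed per letter, which holds fewer samples. For the proximal jejunum against the duodenum (19) it was 11 with total counts, 11 with no filter, 57 without the 13 libraries and 52 with the block as well. For the cecum against the distal jejunum (25) it was 4 with total counts, 46 with the block, 89 without the 13 libraries and 97 with both. For the spiral colon against the cecum (1) it was 0 with total counts, 2 with no filter, 2 with the CPM filter, 5 without the 13 libraries and 9 with the block as well. For the descending against the spiral colon (0) it was 1 with RLE and 1 with the block and without the 13 libraries. List calls (41) were 1 with an estimated correlation, 7 with fry, 35 with total counts and 31 without the 13 libraries. With total counts the median log2 fold change shifted to -0.22 for the large intestine, -0.16 for the cecum against the distal jejunum, and for super-shedders to 0.22 in the duodenum, -0.14 in the proximal and -0.27 in the distal jejunum, 0.32 in the cecum and 0.23 in the spiral colon.

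With 1 letter left out, called miRNAs between statuses ranged from 0 to 1 in the duodenum, proximal jejunum, distal jejunum and cecum, from 0 to 2 in the spiral colon, from 0 to 0 in the descending colon and from 0 to 2 over all regions, and those of the varying shedding difference from 0 to 3. The count was 1 only without letter E in the duodenum, the proximal and distal jejunum and the cecum. In the spiral colon it was 0 without B, G, H, I or J and 2 without D, and over all regions 0 without B, C, D, G, H, I or J and 2 without E or F. Any difference between regions ranged from 40 (J) to 123 (I), the large against the small intestine from 55 (F) to 128 (I), the proximal jejunum against the duodenum from 12 (B and D) to 42 (I), and the cecum against the distal jejunum from 15 (A) to 58 (I). The distal against the proximal jejunum ranged from 0 to 0, the spiral colon against the cecum from 0 (F) to 3 (I), the descending against the spiral colon from 0 to 1, and list calls from 28 (I) to 42 (D).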

Other observations

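The miR-379 cluster, the miR-6526 values, the differences between letters and all but 1 of the comparisons with other splits of the samples in this part were chosen or written down after the results were seen. In the imprinted miR-379 cluster, a large group of miRNA genes read from 1 parental chromosome, 9 of 16 tested members were higher in the large than in the small intestine and 0 were lower, among them miR-154c (0.90 ± 0.17), miR-410 (0.71 ± 0.13), miR-380-3p (0.71 ± 0.15) and miR-411a (0.68 ± 0.18, SE, n = 30 libraries per side). In the cecum against the distal jejunum 10 of 16 were higher and 0 lower. With scaling to total counts 8 were higher and 0 lower in the large intestine, while in the cecum against the distal jejunum 0 passed in edgeR, with 12 at an unadjusted p under 0.05 and a median log2 fold change of 0.83 (1.02 before). That the cluster moves as one set may hold, but it stays open for the large intestine, with an adjusted p of 3.76e-07 by camera at the preset correlation and 0.0657 with an estimated correlation (0.0284 with total counts). In the cecum against the distal jejunum the adjusted p with an estimated correlation was 0.0421 (0.0149 with total counts). By camera at the preset correlation the cluster was also lower in the proximal jejunum than in the duodenum (2 of 16 members positive, adjusted p = 0.00316, and 0.229 with an estimated correlation) and in the spiral colon than in the cecum (0 of 16 positive, 4.21e-04, and 0.215). It was higher in the descending than in the spiral colon (15 of 16 positive, 0.00316, and 0.229), and the distal against the proximal jejunum gave no call (3 of 16 positive, 0.359). In these 4 comparisons 0 single members passed in edgeR, and 1 member in the proximal jejunum against the duodenum and 1 in the spiral colon against the cecum had an unadjusted p under 0.05. Without the 13 libraries the adjusted p at the preset correlation was 0.554 for the spiral colon against the cecum and 0.0969 for the descending against the spiral colon.

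miR-6526 was found mainly in the cecum. It averaged 11.6 ± 11 CPM (SD, n = 10) there, with 8 of 10 libraries over 3 CPM, and between 0.384 and 1.65 CPM in the other 5 regions. The low-count filter removed it from the main tests. With no filter its log2 fold change was 3.91 ± 0.63 in the cecum against the distal jejunum (adjusted p = 4.96e-05, and 7.55e-04 with the letter as a block) and -4.10 ± 0.62 in the spiral colon against the cecum (1.37e-05).

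Animals of the same status differed from each other in 89 of 288 miRNAs, by an edgeR test of letters within status over their 6 regions. The largest F values belonged to miR-99a-5p, miR-100, miR-99b, miR-151-3p and miR-378b, the first 3 of which belong to the miR-99/100 family. Letter I averaged 36503 ± 29024 CPM of miR-100 (SD, n = 6), and the other letters at most 6996 CPM. Without the 13 libraries 40 of 309 miRNAs differed between letters, 27 of them among the 89, with miR-378b at an adjusted p of 2.59e-05. In the real grouping of libraries by letter 89 miRNAs were called, against at most 11 in other splits, and 1 of 100 splits gave as many. That argues against chance, although 1 of 100 is the smallest share that 100 splits can give.

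The duodenum library of letter I held 9635 CPM of miR-122 and 92.7 CPM of miR-885, miRNAs of liver cells, with 66344 CPM of miR-30a-5p and 1046 CPM of miR-193b. The medians of the other 9 duodenum libraries were 0.591, 4.73, 6170 and 89.2 CPM. It held 80.9 CPM of the endocrine miRNA miR-375, 19.1 CPM of the epithelial miR-200c and 1032 CPM of miR-215, against medians of 8086, 763 and 29623 CPM, and 164112 CPM of miR-192 against 119993 CPM. The descending colon library of letter A held 0.848 CPM of miR-378b against an average of 52.3 CPM over the 6 libraries of that letter.

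Other splits of the same libraries were tested as often as the real one was counted, 100 splits each with the real one included. With region labels shuffled within letters, the real labels gave the most calls for any difference between regions (63 calls, highest other 7, 1 of 100 splits as large), the large against the small intestine (78, highest other 2, 1 of 100), the proximal jejunum against the duodenum (19, highest other 13, 1 of 100) and the cecum against the distal jejunum (25, highest other 4, 1 of 100). These counts argue against chance, but 1 of 100 is the smallest share that 100 splits can give and is not adjusted for the number of counts tested. For the proximal jejunum against the duodenum the margin was small. Its count fell below 13 with scaling to total counts and with no low-count filter, so chance is not excluded there. Chance is not excluded for the spiral colon against the cecum (1, highest other 3, 16 of 100), and the 0 calls of the distal against the proximal jejunum (highest other 4) and of the descending against the spiral colon (highest other 26) were reached in 100 of 100 splits. What sets apart the libraries of the split with 26 calls was not tested.

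For shedding, with letters divided anew, 3 of 100 splits gave as many calls over all regions as the real one (1 call, highest other 2). That share is not adjusted for the number of counts tested, and the call was lost without B, C, D, G, H, I or J. It therefore does not exclude chance. Chance is not excluded in the duodenum (1, highest other 2, 5 of 100), the distal jejunum (1, highest other 2, 5 of 100), the spiral colon (1, highest other 19, 9 of 100) or for a difference that varies between regions (1, highest other 3, 49 of 100). The 0 calls of the proximal jejunum (highest other 1), the cecum (highest other 2) and the descending colon (highest other 1) were reached in 100 of 100 splits. The split with 19 calls in the spiral colon set letters A, D, E, F and J against the rest, and the other side held the 3 spiral colon libraries outside the marker rule. What gave its calls was not tested. In 5 of the 100 splits letters A to D stayed together, the real one among them. These called miR-378b in 3 of 5 cases in the duodenum, 3 in the distal jejunum, 3 in the cecum, 5 in the spiral colon, 2 over all regions and 0 in the proximal jejunum and the descending colon, and the other 95 splits called it in 0 cases.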
